A study of Mus musculus with 15 samples.

How the data were processed

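Total RNA was extracted with QIAzol from 15 mouse samples, labelled with biotin and hybridised to Affymetrix Mouse Gene 2.0 ST arrays. The values are log2 expression values deposited by the authors, made by RMA with affy 1.36.1 in R 2.15.1 per the labels, 1 value per probe set and sample. RMA includes background correction, quantile normalization and median polish. The log2 scale was read from the values, since the labels do not state it. The genome build is not given in the sources used here, and no coordinates are used. The table holds 25206 probe sets, each named by an Entrez Gene ID. A symbol was taken from the mouse RefSeq table for 23185 of them, 2021 stayed unnamed, 0 had several symbols and 0 had a symbol updated. The values were used without a further filter. Of the probe sets, 25.6% held the same value in 2 or more samples, and 0 pairs of samples were identical. The sample medians lay between 4.08 and 4.29. No scan dates were in the sources used here, so array batches were not examined.

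Samples were grouped by the labels into day 0 iPSC, day 5 Kdr+, day 13 GFP-, day 13 GFP+ and aortic GFP+, with 3 samples each. The replicate numbers were 3, 5 and 6 for the cultured groups and 1, 2 and 3 for the aortic samples. All 15 samples were fitted in 1 model with a mean per group (limma 3.58.1 in R 4.3.3), with empirical Bayes moderation of the variances (10 residual and 5.09 prior degrees of freedom). There were 5 comparisons: day 5 against day 0, each day 13 sort against day 5, the day 13 sorts against each other, and aortic against day 13 GFP+ cells. The p-values were adjusted by Benjamini and Hochberg within each comparison, with a threshold of 0.05. No replicate block was used, because no text on the methods states a pairing. Errors are standard errors of the moderated log2 difference unless an SD is named. A scaling of the values moved a sample median by at most 0.106 under median centring, 0.107 under a repeated quantile normalization and 0.151 under cyclic loess, so log2 changes are relative to shifts of that size.

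Tests of gene groups used camera from limma with a preset correlation of 0.01 between genes, adjusted over 27 lists with at least 5 measured members. The lists were contractile smooth muscle, synthetic smooth muscle, mural and pericyte, vascular extracellular matrix, fibroblast, TGF-beta responsive, naive pluripotency, general pluripotency, primitive streak, lateral and cardiovascular mesoderm, endothelial, blood progenitor and erythroid, macrophage and leukocyte, cardiac muscle, skeletal muscle, mesothelium and epicardium, epithelial, mesenchymal transition, neural and neural crest, endoderm, adipocyte, proliferation, immediate early and dissociation stress, glycolysis, and Hox paralogs 1 to 4, 5 to 9 and 10 to 13. They were written from general knowledge. Members without a named probe set were not counted as measured. Counts of members are given over all probe sets tested and adjusted over the list alone. Camera with an estimated correlation and fry, which tests whether the genes of a list move one way without comparing them with other genes, were alternatives.

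Genes were named by a fixed rule. The sort genes Kdr and Acta2 were given as checks, though without a Kdr- group Kdr cannot check its sort. Up to 6 genes with the highest and 6 with the lowest log2 change were named among those past the threshold whose 3 samples of one group lay beyond all 3 of the other, without clone or predicted-gene names. Up to 4 members with the largest change were named from each list assigned to a comparison, and up to 2 from every other list. Genes outside the rule are marked as chosen after their values were seen.

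The distance of each day 13 sample to the mean aortic profile was the root mean square log2 difference over the named genes, with an exact two-sided permutation test. The pairing of replicate numbers was checked by correlating, across genes, the deviations of equal and unequal numbers from their group means. Outside day 13, equal numbers correlated between -0.091 and 0.079, so the numbers did not pair the other stages. The comparison of the day 13 sorts was tested on simulated data of the same size and groups with 25206 genes. The simulated samples were drawn independently, without any pairing by replicate number. The fit found 14 of 67 genes changed by 0.5 on the log2 scale (20.9%), 53 of 67 changed by 1 (79.1%) and 64 of 66 changed by 2 (97%), and 3 of 134 calls were false (2.24%). For the signs of the 2 day 13 sorts against their shared day 5 samples, 20 sets of unchanged groups were simulated, without and with a correlation between day 13 samples of equal number, a step added after the data were seen.

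Alternatives were a fit on only the 2 groups compared, array weights, variance moderation with a trend or robust, treat with a log2 change of 1, median centring, repeated quantile normalization, cyclic loess, genes above the median mean level, a replicate block as a fixed or random effect, estimated correlation, fry, and leaving out each sample in turn. A block on the 6 day 13 samples and leaving out both day 13 samples numbered 3 were added after the data were seen. Figures were drawn with matplotlib 3.10.9. Splice forms and raw array images were not analysed here.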

Results

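Gene expression was profiled on arrays in 15 samples that follow mouse induced pluripotent stem cells (iPSC) towards smooth muscle. The line carries Acta2hrGFP, a reporter in which a green fluorescent protein (GFP) marks activity of Acta2, the smooth muscle actin gene. The 5 groups of 3 samples were iPSC at day 0, cells sorted at day 5 for Kdr (Flk1, a VEGF receptor of early mesoderm), GFP- and GFP+ cells sorted at day 13, and GFP+ smooth muscle cells from the aorta. The 75th percentiles of the samples lay between 5.929 and 6.199 on the log2 scale of the deposited RMA values. With 3 arrays per group, their number limits the precision of every value. The labels call the samples biological triplicates and say nothing more on how separate the cultures were, so each p-value rests on the spread between these triplicates. The gene lists, the tests and the rule for naming genes were chosen before the data were examined, except where a fit, a test or a gene is said to have been chosen after. The files hold no calls of presence, so low levels such as Nr0b1 at 2.31 or Aoc3 at 2.35 are not shown to lie above background. Folds against such levels, and the ranks by fold, depend in part on the floor of the array. The number of genes in each direction depends on the scaling of the arrays as well, and after cyclic loess the direction with more genes turned in each of the 5 comparisons.

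Pairs of samples within a group correlated across genes at r from 0.977 to 0.995, where genes are not independent replicates. Against the aortic samples, r was 0.799 to 0.809 for day 0, 0.815 to 0.831 for day 5, 0.869 to 0.888 for day 13 GFP- and 0.89 to 0.899 for day 13 GFP+. The GFP- and GFP+ samples of day 13 correlated with each other at 0.965 to 0.988. The first principal component held 50.8% of the variance, the second 23.3%, the third 12.9% and the fourth 3.36%. On the fourth component both day 13 samples numbered 3 lay on the other side of 0 from the day 13 samples numbered 5 and 6.

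**Figure D1:**
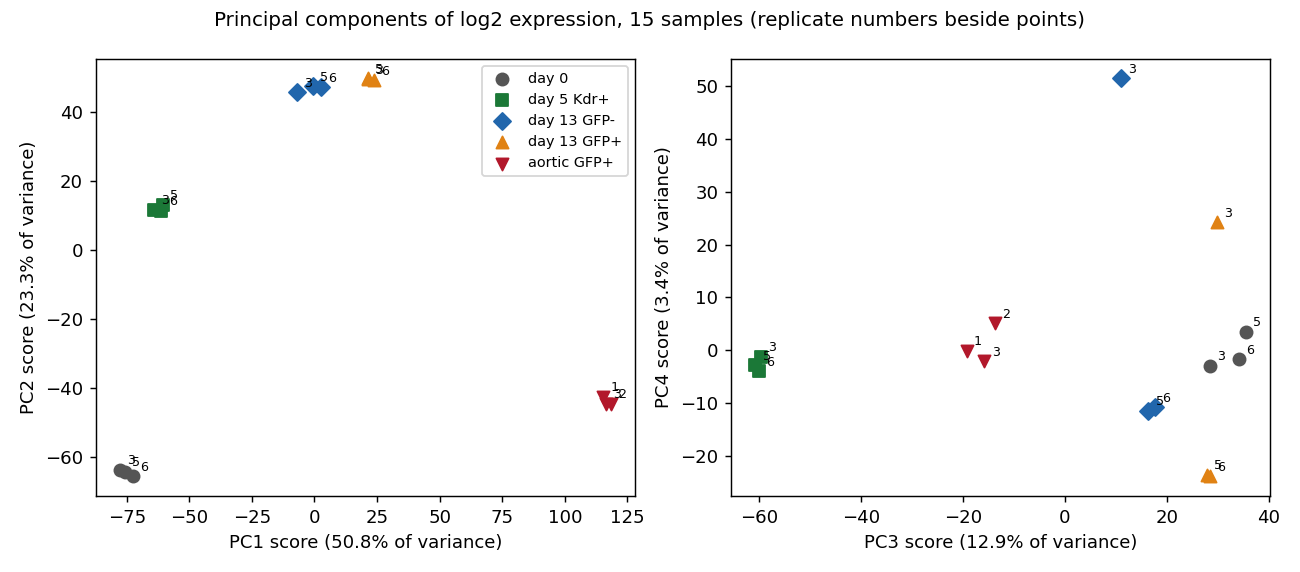
Principal component scores of the 15 samples from log2 expression, each point 1 sample with its replicate number, with the first and the second component on the left and the third and the fourth component on the right. The aortic samples lie at the far end of the first component, and the day 13 samples numbered 3 lie apart from those numbered 5 and 6 on the fourth component.

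The day 5 Kdr+ cells were compared with day 0 to follow the exit from pluripotency into mesoderm. Mixl1 (probe set 27217_at), a homeobox gene of the primitive streak, rose from 3.70 ± 0.339 to 10.87 ± 0.123 (SD, n = 3), a log2 change of 7.17 (SE 0.333, 144-fold, limma adjusted p = 2.28e-10). Bmp4 (12159_at), a ligand that patterns ventral mesoderm, rose 50.1-fold from a mean of 4.59 to 10.24 (SE 0.298, adjusted p = 9.46e-10). Nr0b1 (11614_at), part of the pluripotency network, fell from 8.73 to 2.31, a measured 85.6-fold (SE 0.129, adjusted p = 4.04e-14), and the E-cadherin gene Cdh1 fell 23.2-fold from 9.40 to 4.86 (adjusted p = 5.5e-11). Kdr itself, the sort marker, stood at 3.24 at day 0 and 9.64 at day 5 (84.7-fold). Without a Kdr- or unsorted day 5 group, this rise cannot check the sort. Acta2 was lower at day 5, 5.93 against 7.01 (limma adjusted p = 0.00175). Of 25206 probe sets, 3744 rose and 3505 fell at adjusted p under 0.05, 28.8% of those tested, and 1318 and 1556 of these changed at least 2-fold. After median centring 4475 rose and 2911 fell, and after cyclic loess 3354 and 3857. The 3 values of one group lay wholly beyond the 3 of the other in 46% of probe sets, where chance gives 10%. The other genes of largest increase were Capn6 (98-fold), Amot (93.7-fold) and Rgs5 (58.6-fold), and those of largest decrease were Zfp981 (82.7-fold), Pla2g1b (log2 change -5.96), Dnmt3l (57.5-fold), Elobl (log2 change -5.71) and Utf1 (44.6-fold).

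Among the gene lists, the pluripotency genes fell together and the mesoderm genes rose together. Of 13 measured naive pluripotency genes 12 fell and 1 rose (13 adjusted over the list alone, median log2 change -4.09, camera adjusted p = 6.57e-15), among them Tcl1 (-4.72), Tfcp2l1 (-4.59) and Fgf4 (-4.55). Of 13 general pluripotency genes 8 fell, 2 rose and 3 did not pass (10 over the list alone, median -3.00, adjusted p = 3.33e-06). The primitive streak list had 13 of 14 members higher (13 over the list alone, adjusted p = 3.6e-11), with Eomes at 5.25, Lhx1 at 4.71 and Wnt3 at 4.18. The lateral and cardiovascular mesoderm list had 12 of 16 higher (12 over the list alone, median 3.18, adjusted p = 7.29e-11), with the cardiac transcription factors Hand1 and Tbx20 each at 4.93. Epithelial genes moved the opposite way to mesenchymal ones. Of 11 epithelial genes 9 fell and 2 rose (11 over the list alone, adjusted p = 9.08e-06), Cldn4 by 26.5-fold, while the keratin gene Krt8 rose (3.05). Of 10 mesenchymal transition genes 8 rose and 2 did not pass (8 over the list alone, adjusted p = 4.2e-06), with N-cadherin Cdh2 up 23.4-fold and Zeb2 at 3.09.

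Several lists outside the mesoderm programme moved at day 5 as well. The immediate early and dissociation stress list fell in 15 of 17 members (15 over the list alone, median -1.52, adjusted p = 1.08e-11), with Fos 10.4-fold lower. The macrophage and leukocyte list fell in 8 of 12 members (8 over the list alone, adjusted p = 0.000123), led by the lysosomal membrane gene Laptm5 (-5.18). Glycolysis genes fell in 10 of 13 members (11 over the list alone, median -1.91, adjusted p = 1.54e-07), with Pfkp 19.6-fold lower, but this call had adjusted p = 0.276 with an estimated correlation. The other 8 camera calls of this comparison held with an estimated correlation, at larger camera adjusted p, from 0.000154 (naive pluripotency) to 0.0449 (epithelial). The remaining 18 lists did not pass. In the endothelial list 4 of 17 members fell and 1 rose (5 over the list alone, adjusted p = 0.0995), and Pecam1 fell 11-fold from 7.99 to 4.53. In the blood progenitor and erythroid list 2 of 13 members rose and 1 fell (3 over the list alone, adjusted p = 0.828), with Runx1 up 11.8-fold. The contractile smooth muscle list had 5 members higher and 3 lower of 19 (8 over the list alone, adjusted p = 0.371). The skeletal muscle list had 0 of 13 members past the limma threshold, 0 over the list alone and 0 at 0.05 without adjustment (camera adjusted p = 0.917, fry adjusted p = 0.708). The median was of the opposite sign to the mean or the test in the mural and pericyte (median -0.08, mean 0.73), fibroblast, cardiac, skeletal, mesothelium and endoderm lists, none of which passed.

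The day 13 GFP- cells were compared with the day 5 progenitors to show what changed in differentiated cells without reporter activity. The day 5 samples are also the reference of the next comparison. Clu (12759_at), which encodes the secreted chaperone clusterin, rose from 4.56 to 10.85, a log2 change of 6.28 (SE 0.18, 77.9-fold, adjusted p = 1.62e-11, n = 3 per group by limma). Pga5 (58803_at), a pepsinogen gene of the gastric lining, rose 45.9-fold from 3.83 to 9.35 (SE 0.164). Tagln (21345_at), an actin-binding smooth muscle gene, rose 12.9-fold from 4.67 to 8.36 (SE 0.165). Lox, which crosslinks collagen and elastin, rose 61.4-fold to a mean of 8.85 ± 1.25 (SD, n = 3), with adjusted p = 4.78e-08, and 101-fold without GFP- sample 3. In all, 3036 probe sets rose and 3506 fell, 26% of those tested, 1421 and 1154 of them at least 2-fold (3446 and 3153 after cyclic loess), and the groups did not overlap in 39.6% of probe sets, where chance gives 10%. Srgn rose 74.1-fold, and Col12a1 (5.73, and 6.57 without GFP- sample 3) and Ankrd1 (5.67) followed. Mixl1 (-5.42), Tdgf1 (-5.02), Hand1 (-4.63), Rps6ka6 (-4.14), Phlda2 (-3.83) and Foxf1 (-3.66) fell most. Acta2 rose from 5.93 to 10.67 ± 0.447 in these GFP- samples (log2 change 4.74).

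In GFP- cells the contractile smooth muscle list had 14 of 19 members higher (15 adjusted over the list alone, median 1.02, adjusted p = 1.04e-11), with Des at 2.70 and Myl9 at 2.35. The vascular extracellular matrix list had 17 of 19 higher (17 over the list alone, median 2.27, adjusted p = 6.17e-15), including the collagen genes Col3a1 (5.10) and Col1a2 (4.67, and 5.28 without GFP- sample 3). The endoderm list had 10 of 13 members higher and 1 lower (11 over the list alone, median 1.23, adjusted p = 1.63e-08), with the pancreatic trypsin inhibitor gene Spink1 up 42.3-fold from 3.11 to 8.51 and apolipoprotein B gene Apob up 15.7-fold. The endothelial list had 10 of 17 higher (10 over the list alone, adjusted p = 1.75e-06), with VE-cadherin Cdh5 up 6.23-fold from 4.24 to 6.88 and Erg at 2.52. All 28 proliferation genes fell (28 over the list alone, median -1.26, adjusted p = 8.04e-19), with Rrm2 at -2.19. Synthetic smooth muscle (7 of 10 higher, 9 over the list alone), TGF-beta responsive (6 higher, 1 lower of 11, 9 over the list alone) and immediate early genes (15 of 17 higher, 17 over the list alone) rose with adjusted p = 9.86e-07, 1.05e-05 and 1.95e-13. The primitive streak list fell in 12 of 14 members (12 over the list alone, adjusted p = 3.81e-09). These 9 calls held with an estimated correlation, at larger camera adjusted p, from 0.00564 (contractile among others) to 0.0191 (immediate early).

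A further 7 calls in GFP- cells did not hold with an estimated correlation. The cardiac muscle list had 9 of 17 members higher (9 over the list alone, median 1.58, adjusted p = 8.89e-06), with the troponin gene Tnni1 up 15.3-fold and Tnnt2 10.5-fold (adjusted p = 0.0868 with an estimated correlation). The lateral and cardiovascular mesoderm list had 9 of 16 lower and 1 higher (10 over the list alone, adjusted p = 0.00243, and 0.0868 with an estimated correlation). The fibroblast list had 7 of 12 higher and 1 lower (8 over the list alone, adjusted p = 0.00337, and 0.213 with an estimated correlation). General pluripotency genes fell in 7 of 13 members and rose in 1 (8 over the list alone, adjusted p = 0.00119, and 0.122 with an estimated correlation). In the epithelial list 5 of 11 members rose and 2 fell (7 over the list alone, adjusted p = 0.018, and 0.24 with an estimated correlation), with Cldn6 at 3.33 and Cdh1 at 2.35. Hox 10 to 13 genes rose in 7 of 12 members (7 over the list alone, adjusted p = 0.000537, and 0.123 with an estimated correlation). Glycolysis genes rose in 4 of 13 members (5 over the list alone, adjusted p = 0.00648, and 0.474 with an estimated correlation), and without day 13 GFP- sample 3 this call had adjusted p = 0.124. The median and the mean differed in sign in the mural, mesothelium and neural lists, which did not pass.

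The day 13 GFP+ cells, the candidate smooth muscle cells, were compared with the same day 5 progenitors. Lox (16948_at) rose from 2.91 ± 0.165 to 10.21 ± 0.438 (SD, n = 3), a log2 change of 7.30 (SE 0.417, 158-fold, limma adjusted p = 2.91e-09). Col3a1 (12825_at), a fibrillar collagen gene, rose 89-fold from 3.57 to 10.04 (adjusted p = 2e-10). Tagln rose 26.4-fold to 9.39 ± 0.0845 (SE 0.165, adjusted p = 2.33e-11). The enteric smooth muscle actin gene Actg2 rose 12.6-fold from 3.26 to 6.92, and the myosin light chain gene Myl9 rose 12-fold from 5.64 to 9.22. Here 3598 probe sets rose and 4269 fell, 31.2% of those tested, 1786 and 1919 of them at least 2-fold (4160 and 3700 after cyclic loess). The groups did not overlap in 45.3% of probe sets, where chance gives 10%. Col12a1 (123-fold), Postn (120-fold, and 181-fold without GFP+ sample 3), Igfbp7 (87.6-fold) and Thbs1 (79.4-fold) were among the largest increases, and Mixl1 (132-fold), Tdgf1 (-5.78), Rps6ka6 (-5.38), Eomes (-4.79), Foxh1 (-4.66) and Msx2 (-4.41) were the largest decreases. Acta2 rose 42-fold to 11.32 ± 0.129.

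In GFP+ cells 18 of 19 contractile genes rose (18 adjusted over the list alone, median 1.19, adjusted p = 1.26e-13), and 18 of 19 matrix genes rose (18 over the list alone, median 3.39, adjusted p = 8.73e-18). The TGF-beta responsive (9 of 11 higher, 9 over the list alone), synthetic smooth muscle (8 of 10, 9 over the list alone) and mural and pericyte lists (5 higher, 1 lower of 10, 8 over the list alone) rose with adjusted p = 6.25e-08, 5.05e-07 and 0.00431. All 28 proliferation genes fell (28 over the list alone, median -1.88, adjusted p = 2.24e-22), including the replication licensing genes Mcm5 (8.3-fold) and Mcm7 (-2.71). The primitive streak list fell in 10 of 14 members (11 over the list alone, adjusted p = 8.74e-09), and the immediate early list rose in 15 of 17 (16 over the list alone, median 1.65, adjusted p = 6.04e-12). These 8 calls held with an estimated correlation, at larger camera adjusted p, from 0.00347 (contractile among others) to 0.0313 (mural and immediate early). Endoderm genes did not pass as a list (1 higher, 1 lower of 13, 2 over the list alone, adjusted p = 0.69), nor did endothelial genes (3 of 17 higher, 3 over the list alone, adjusted p = 0.108), and Cdh5 changed by 0.54 (adjusted p = 0.279). The naive pluripotency list did not pass (3 higher, 4 lower of 13, 7 over the list alone, adjusted p = 0.556). Its median and mean differed in sign, as they did in the mesothelium, neural and endoderm lists.

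A further 8 calls in GFP+ cells were lost with an estimated correlation. Hox 10 to 13 genes rose in 8 of 12 members (8 over the list alone, median 1.20, adjusted p = 1.37e-05, and 0.0662 with an estimated correlation), with Hoxd13 up 5.88-fold and Hoxd11 at 2.19. Hox 5 to 9 genes rose in 6 of 15 members (6 over the list alone, adjusted p = 0.00895, and 0.113 with an estimated correlation). Cardiac muscle genes rose in 8 of 17 members (8 over the list alone, adjusted p = 0.000459, and 0.138 with an estimated correlation), with Tnni1 up 13.6-fold and Tnnt2 11-fold. Fibroblast genes rose in 8 of 12 and fell in 1 (9 over the list alone, adjusted p = 0.000363, and 0.113 with an estimated correlation). General pluripotency genes fell in 6 of 13 (7 over the list alone, adjusted p = 0.000125, and 0.0673 with an estimated correlation). The lateral and cardiovascular mesoderm list fell in 10 of 16 members and rose in 2 (12 over the list alone, adjusted p = 0.000932, and 0.0662 with an estimated correlation). In the epithelial list 5 of 11 members fell and 1 rose (6 over the list alone, adjusted p = 0.0477, and 0.303 with an estimated correlation). The epithelial call ended without day 5 sample 5 (adjusted p = 0.0503), without GFP+ sample 5 (0.051) and without GFP+ sample 6 (0.0716), and after median centring (0.06). Glycolysis genes rose in 4 of 13 members (5 over the list alone, adjusted p = 0.0477, and 0.613 with an estimated correlation). The glycolysis call ended without day 5 sample 5 (adjusted p = 0.0503), day 5 sample 6 (0.0651) or GFP+ sample 3 (0.314). The mesenchymal transition list did not pass (6 higher, 2 lower of 10, 8 over the list alone, adjusted p = 0.05), and passed without day 5 sample 5 (0.0338) or day 5 sample 6 (0.0499) and after median centring (0.031), quantile normalization (0.0323) or cyclic loess (0.0298).

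**Figure D2:**
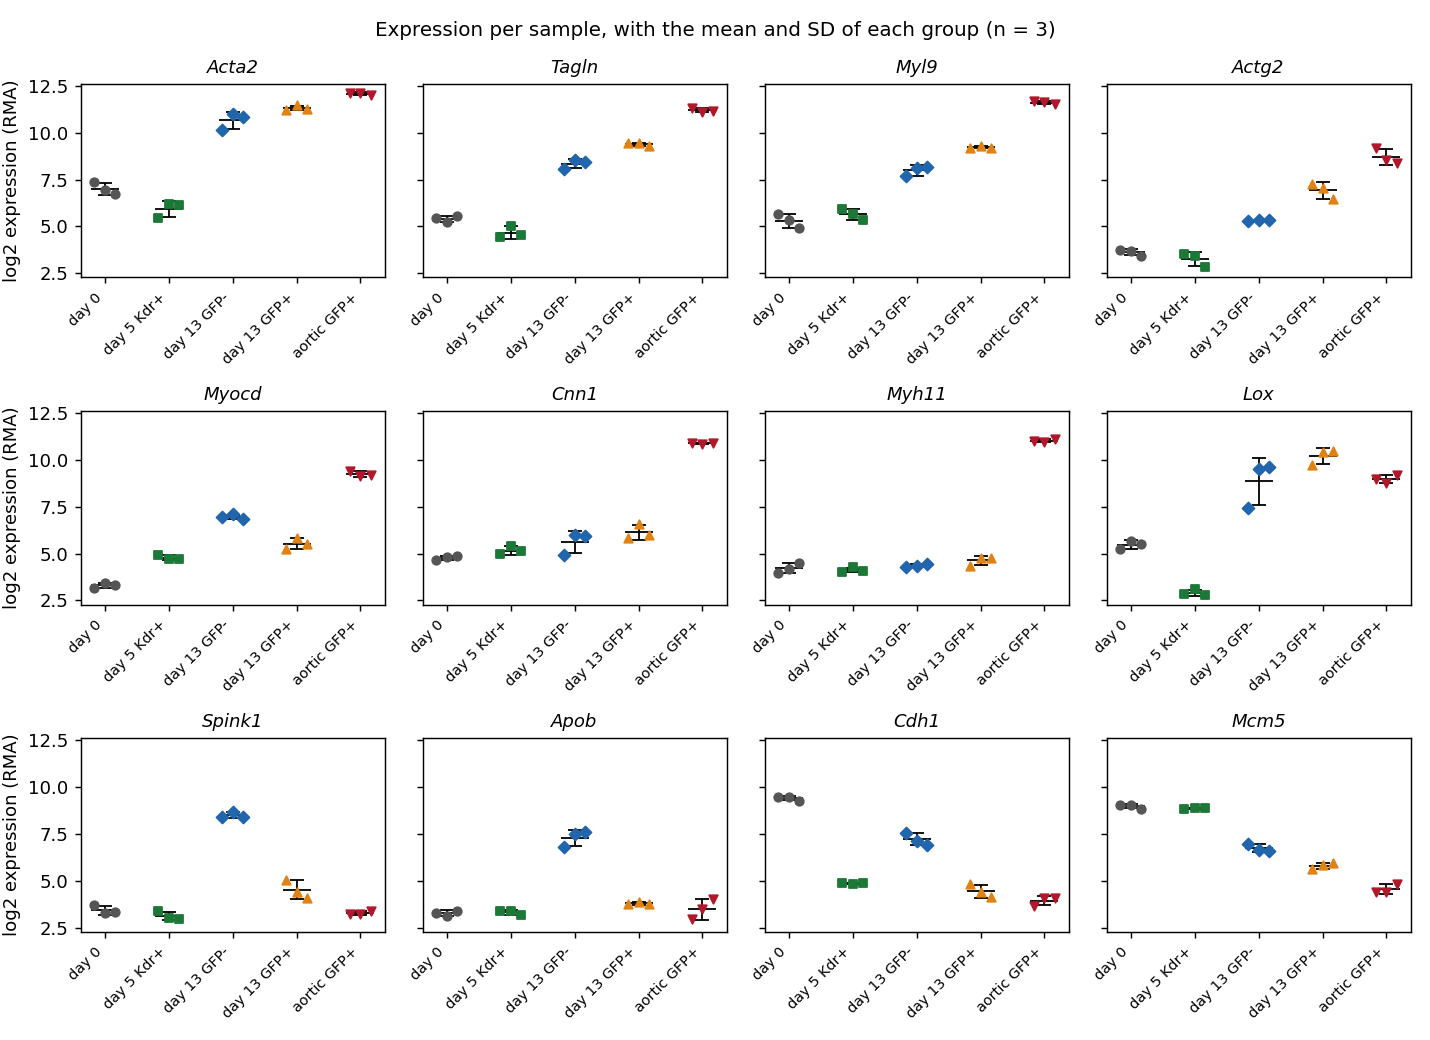
Log2 expression (RMA) of 12 genes in each of the 15 samples, with the mean and SD of each group of 3 in black. Acta2, Tagln, Myl9 and Actg2 rise at day 13 and are highest in the aortic samples, Myh11 and Cnn1 are far higher in the aortic samples than in the other groups, and Spink1, Apob and Cdh1 are higher in GFP- than in GFP+ cells.

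The 2 sorts of day 13 were compared directly, which asks what goes with reporter activity. Pga5 was lower in GFP+ cells, 5.34 ± 0.202 against 9.35 ± 0.0807 in GFP- cells (SD, n = 3), a log2 difference of -4.01 (SE 0.164, 16.2-fold, limma adjusted p = 3.66e-09). Spink1 (20730_at) was 16-fold lower at 4.52 against 8.51 (SE 0.207, adjusted p = 5.94e-08). Il1r1 (16177_at), an interleukin receptor gene, was 3.87-fold higher in GFP+ cells at 6.59 against 4.64 (SE 0.183, adjusted p = 1.44e-05). Actg2 was 3.01-fold higher at 6.92 against 5.33 (SE 0.232, adjusted p = 0.00083), and Myl9 2.34-fold higher (SE 0.188, adjusted p = 0.00124). Myocd (214384_at), a transcriptional coactivator of cardiac and smooth muscle genes, was lower in GFP+ cells, 5.53 ± 0.278 against 6.97 ± 0.112 (2.71-fold, SE 0.147, adjusted p = 3.34e-05). The sort gene Acta2 differed by 0.65 (SE 0.229, adjusted p = 0.151), and Kdr by -0.30 (adjusted p = 0.573). In all, 508 probe sets were higher and 634 lower in GFP+ cells, 4.53% of those tested, 162 and 223 of them at least 2-fold (605 and 537 after cyclic loess). The groups did not overlap in 19.5% of probe sets, where chance gives 10%. Without GFP- sample 5 the counts were 310 and 419, and without GFP+ sample 6 they were 307 and 346. Ulbp1 (4.07-fold), Lpl (3.99-fold), Srpx2 (3.99-fold), Anxa8 (3.6-fold) and Glipr1 (3.55-fold) were the other genes most raised. Srgn (12.4-fold), Apob (11.3-fold), Car4 (10.8-fold) and Trh (9.23-fold) were the others most reduced. Fitted on only the 2 groups, far fewer probe sets passed in either direction, as counted in the part on processing. In that fit Lpl did not pass (limma adjusted p = 0.0614). Chosen after their values were seen, Tagln was higher by 1.04 (adjusted p = 0.00167), while Cnn1 (0.52, adjusted p = 0.347) and Myh11 (0.28, adjusted p = 0.431) did not pass.

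The day 13 samples showed some pairing by replicate number, clearest for number 3. After the group mean was removed, samples numbered 3, 5 and 6 correlated across genes between the 2 sorts at 0.597, 0.403 and 0.397, each highest with its own number. The highest correlation of these GFP- samples with a GFP+ sample of another number was -0.419, 0.278 and 0.345. Deviations from a group mean offset each other, so the departure of number 3 makes numbers 5 and 6 correlate whatever their pairing. With the replicate number as a block on the 6 day 13 samples, a fit added after the data were seen, 1045 probe sets were higher and 1085 lower in GFP+ cells. Of the 1142 unblocked calls 1072 remained under the block, all in the same direction, and 70 did not. Under the block Pga5 had adjusted p = 5.02e-05, Il1r1 0.000966, Actg2 0.00175, Myl9 0.00186 and Myocd 0.000944, and Acta2 passed with 0.0362 (SE 0.149).

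Of the lists, the endoderm and epithelial genes were lower in GFP+ cells and the matrix and contractile genes higher. The endoderm list had 10 of 13 members lower (10 adjusted over the list alone, median -1.10, adjusted p = 3.24e-23), with the apolipoprotein gene Apoa1 5.77-fold and alpha-fetoprotein Afp 4.05-fold lower. The epithelial list had 8 of 11 lower (9 over the list alone, median -1.35, adjusted p = 1.24e-19), Cdh1 by 6.76-fold and the tight junction gene Cldn6 by 8.23-fold. The matrix list had 8 of 19 higher (17 over the list alone, median 1.09, adjusted p = 1.34e-16), with the crosslinking enzyme gene Loxl1 2.63-fold higher (adjusted p = 1.59e-05) and Col6a3 2.85-fold higher (adjusted p = 0.093 when fitted on only the 2 groups). The contractile list had 6 of 19 higher and 1, Myocd, lower (11 over the list alone, median 0.47, adjusted p = 3.05e-08). Mural and pericyte (3 of 10, 5 over the list alone), TGF-beta responsive (3 of 11, 6 over the list alone) and synthetic smooth muscle genes (2 of 10, 4 over the list alone) were higher with adjusted p = 4.87e-06, 1.49e-06 and 0.00106, including Pdgfrb (1.08), Itgb5 (1.10) and Mmp2 (1.07). The endothelial list had 4 of 17 lower and 1 higher (5 over the list alone, adjusted p = 3.02e-05), with Cdh5 4.3-fold, Pecam1 (-1.28) and Sox17 (-1.10) lower. The proliferation list had 12 of 28 lower (23 over the list alone, median -0.61, adjusted p = 8.48e-21), among them Mcm7 (-1.05) and Mcm5 (-0.93). General pluripotency genes were lower in 5 of 13 (6 over the list alone, adjusted p = 5.92e-06), with Sall4 at -2.13 and Dnmt3b at -2.02. These 10 calls held with an estimated correlation, at far larger camera adjusted p, from 0.000262 (endoderm) to 0.0412 (synthetic smooth muscle), with 0.0127 for proliferation. Under the block on the 6 day 13 samples, 17 matrix, 8 contractile, 5 mural, 6 TGF-beta responsive and 2 synthetic members were higher. Under that block 10 endoderm, 9 epithelial, 16 proliferation and 6 general pluripotency members were lower, with 1 contractile member lower and, of the endothelial list, 5 lower and 2 higher.

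A further 5 calls between the sorts did not hold with an estimated correlation. Hox 10 to 13 genes were higher in 2 of 12 members (4 over the list alone, adjusted p = 2.68e-05, and 0.0699 with an estimated correlation). The primitive streak list was lower in 4 of 14 (4 over the list alone, adjusted p = 0.00192, and 0.152 with an estimated correlation), with Lhx1 at -2.61. The fibroblast list had 0 of 12 members past the limma gene test, 0 over the list alone and 2 at 0.05 without adjustment, although the list passed (median 0.65, fry adjusted p = 0.0681, camera adjusted p = 0.00194, and 0.169 with an estimated correlation), and 7 members were higher under the block. Hox 5 to 9 genes were higher in 1 of 15 (1 over the list alone, adjusted p = 0.00859, and 0.116 with an estimated correlation), and without GFP+ sample 5 the adjusted p was 0.053. The mesenchymal transition list had 2 of 10 higher (4 over the list alone, adjusted p = 0.0458, and 0.0941 with an estimated correlation). It did not pass without GFP- sample 3 (0.0608), GFP+ sample 3 (0.055) or GFP+ sample 5 (0.0808), nor under the block (0.0684). The cardiac muscle list did not pass (1 of 17 lower, 1 over the list alone, adjusted p = 0.239), and passed as lower in GFP+ cells without GFP- sample 3 (0.00116) and under the block (0.035). The immediate early list did not pass (1 of 17 higher, 2 over the list alone, adjusted p = 0.05), and passed without GFP- sample 5 (0.0428) or GFP+ sample 3 (0.000433) and after median centring (0.0476), quantile normalization (0.0147) or cyclic loess (0.00459). The glycolysis list did not pass (1 of 13 lower, 1 over the list alone, adjusted p = 0.509) and was lower without GFP+ sample 3 (0.00138). Macrophage and leukocyte genes did not pass by limma (0 of 12, 0 over the list alone and 0 at 0.05 without adjustment, camera adjusted p = 0.585, fry adjusted p = 0.622). Blood progenitor and erythroid genes did not either (0 of 13, 0 over the list alone and 1 at 0.05 without adjustment, camera adjusted p = 0.568, fry adjusted p = 0.577). The median and the mean differed in sign in the naive pluripotency, neural and Hox 1 to 4 lists, which did not pass.

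The aortic GFP+ cells served as the positive control, and their comparison with day 13 GFP+ cells asks how far the differentiated cells lay from primary smooth muscle. Primary cells from the aorta also differ from the cultured cells in source and handling. These cannot be told apart from smooth muscle maturity in this comparison. Aoc3 (11754_at), a vascular amine oxidase gene, was higher in the aortic cells, 9.66 against 2.35, a log2 difference of 7.31 (SE 0.13, a measured 159-fold, limma adjusted p = 4.84e-15, n = 3 per group). Myh11 (17880_at), the smooth muscle myosin heavy chain gene, stood at 11.03 ± 0.071 against 4.64 ± 0.243 (83.5-fold, SE 0.15, adjusted p = 9.18e-14). The calponin gene Cnn1 was 26.9-fold higher at 10.89 against 6.14 (adjusted p = 5.01e-10). Mest (17294_at), an imprinted gene of growing tissue, was 117-fold lower at 4.58 against 11.46 (SE 0.229, adjusted p = 3.35e-12). The sort gene Acta2 was 1.71-fold higher in the aortic cells at 12.10 (adjusted p = 0.0145), and Kdr differed by -1.39. In all, 4449 probe sets were higher and 4923 lower, 37.2% of those tested, 1764 and 2007 of them at least 2-fold (4379 and 4054 after cyclic loess). The groups did not overlap in 44.9% of probe sets, where chance gives 10%. Ecm2 (141-fold), Ccn3 (129-fold), Cd200 (121-fold), Entpd1 (106-fold) and Mustn1 (99.2-fold) were the other genes most raised, and Slc38a4 (102-fold), H19 (99.8-fold), Fbn2 (65.6-fold), Ptn (-5.88) and Itm2a (-5.21) the others most reduced.

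Contractile genes were higher in the aortic cells in 16 of 19 members (16 adjusted over the list alone, median 3.05, adjusted p = 9.61e-16), with Synpo2 40.2-fold and the potassium channel subunit gene Kcnmb1 25.6-fold higher. Mural and pericyte genes were higher in 8 of 10 and lower in 1 (9 over the list alone, median 1.77, adjusted p = 2.32e-06), with Abcc9 57.4-fold higher. The proliferation list was lower in 27 of 28 (27 over the list alone, median -2.52, adjusted p = 7.98e-24), with the topoisomerase gene Top2a 29.3-fold lower, 3.17 against 8.04. All 17 immediate early and dissociation stress genes were higher (17 over the list alone, median 2.64, adjusted p = 1.54e-15), with Atf3 37.7-fold and Nr4a1 30.1-fold higher. The endothelial list (10 of 17 higher, 10 over the list alone, adjusted p = 0.000267) and the macrophage and leukocyte list (10 of 12, 11 over the list alone, adjusted p = 0.000183) were also higher, with Pecam1 13.4-fold, Esam 11.1-fold and Cd14 9.69-fold. These 6 calls held with an estimated correlation, where the camera adjusted p of the contractile list was 0.00454. The matrix list did not pass (6 higher, 6 lower of 19, 12 over the list alone, adjusted p = 0.678), nor did the TGF-beta responsive list (5 higher, 2 lower of 11, 7 over the list alone, adjusted p = 0.349), which passed after cyclic loess (0.0233). The microfibril gene Mfap5 was 42.4-fold and elastin Eln 5.72-fold higher. The adipocyte list did not pass (3 of 10 higher, 3 over the list alone, adjusted p = 0.116), and the fatty acid binding gene Fabp4 was 75.8-fold higher. The neural and neural crest list did not pass (1 higher, 2 lower of 14, 3 over the list alone, adjusted p = 0.745), nor did the mesothelium and epicardium list (1 higher, 2 lower of 10, 3 over the list alone, adjusted p = 0.745). In the neural and blood lists the median and the mean differed in sign.

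A further 7 calls against the aortic cells did not hold with an estimated correlation. Hox 1 to 4 genes were higher in 6 of 11 members (6 over the list alone, adjusted p = 0.00322, and 0.161 with an estimated correlation), with Hoxa2 7.25-fold higher. Hox 10 to 13 genes were lower in 7 of 12 (8 over the list alone, median -1.03, adjusted p = 0.000342, and 0.161 with an estimated correlation), with Hoxd13 6.14-fold lower. Hox 5 to 9 genes were higher in 8 of 15 and lower in 1 (10 over the list alone, adjusted p = 0.0417, and 0.291 with an estimated correlation). The Hox 5 to 9 call ended without GFP+ sample 3 (0.111), aortic sample 1 (0.0552) or aortic sample 2 (0.0886), and after quantile normalization (0.0511) or cyclic loess (0.123). The cardiac muscle list was lower in 9 of 17 and higher in 1 (10 over the list alone, adjusted p = 0.0116, and 0.347 with an estimated correlation), with Tnni1 26-fold and Tnnt2 12.3-fold lower. Glycolysis genes were lower in 8 of 13 (9 over the list alone, adjusted p = 0.00132, and 0.421 with an estimated correlation), with the glucose transporter gene Slc2a3 25-fold lower. Fibroblast genes were higher in 6 of 12 (6 over the list alone, adjusted p = 0.00132, and 0.231 with an estimated correlation), with Dpt 78.3-fold and decorin Dcn 13.8-fold higher (8.18-fold without GFP+ sample 3). The epithelial list was lower in 4 of 11 (4 over the list alone, adjusted p = 0.0417, and 0.347 with an estimated correlation), and did not pass without GFP+ sample 3 (0.102), aortic sample 1 (0.0665) or aortic sample 2 (0.0641). The lateral and cardiovascular mesoderm list did not pass (4 higher, 7 lower of 16, 11 over the list alone, adjusted p = 0.0747), and passed as lower without GFP+ sample 5 (0.0497) or aortic sample 2 (0.0308). The general pluripotency list did not pass (4 of 13 lower, 4 over the list alone, adjusted p = 0.0747), and passed without GFP+ sample 6 (0.0363) and after quantile normalization (0.0499).

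**Figure D3:**
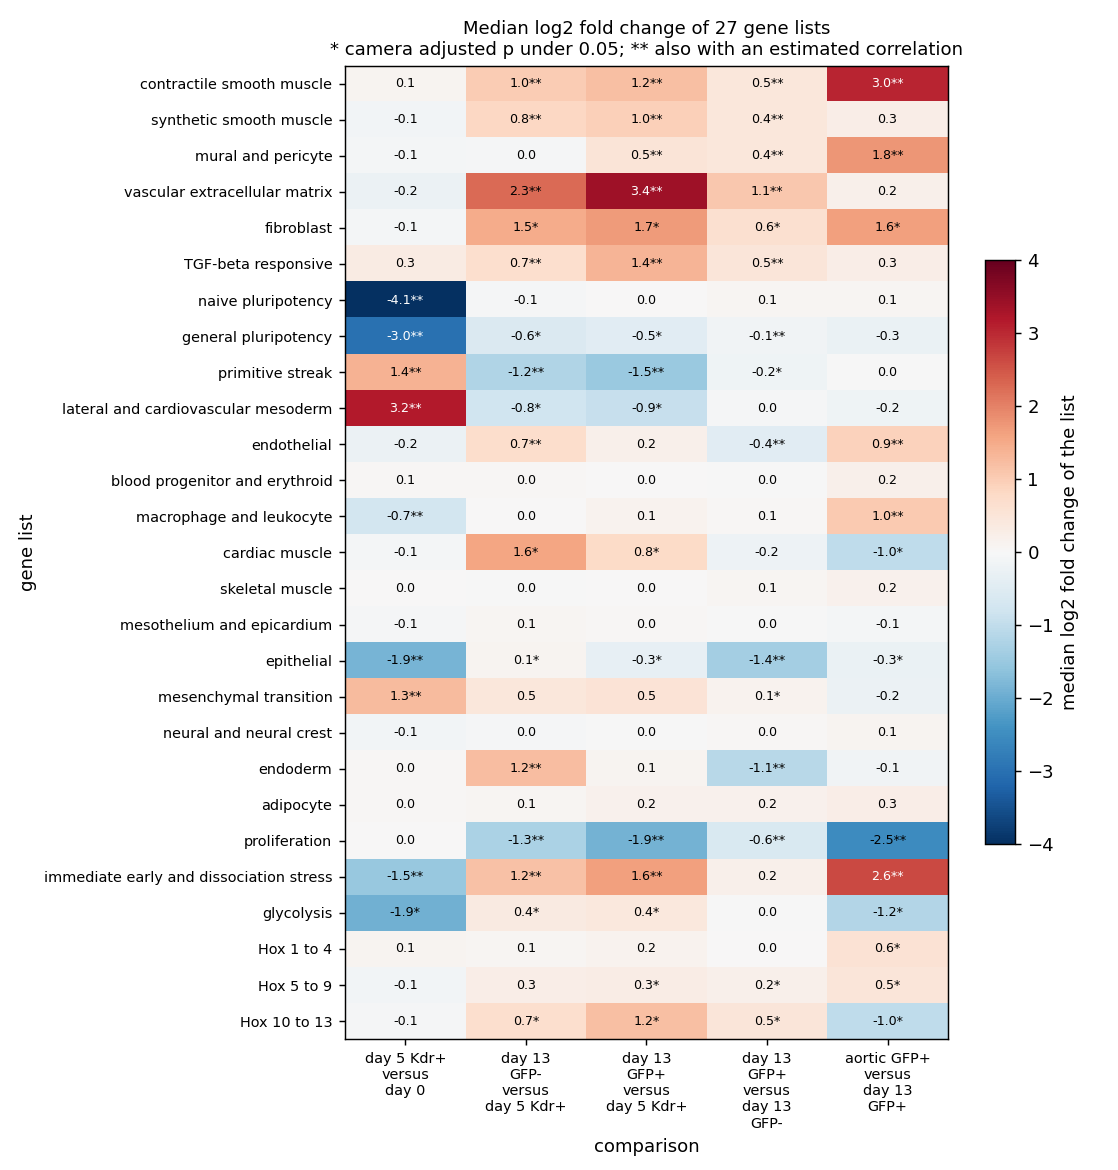
Median log2 fold change of each of the 27 gene lists in the 5 comparisons, with 1 star for a camera adjusted p under 0.05 and a pair of stars where it also held with an estimated correlation. Contractile genes have positive medians in all 5 comparisons, and proliferation genes have negative medians in each comparison but day 5 against day 0.

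**Figure D4:**
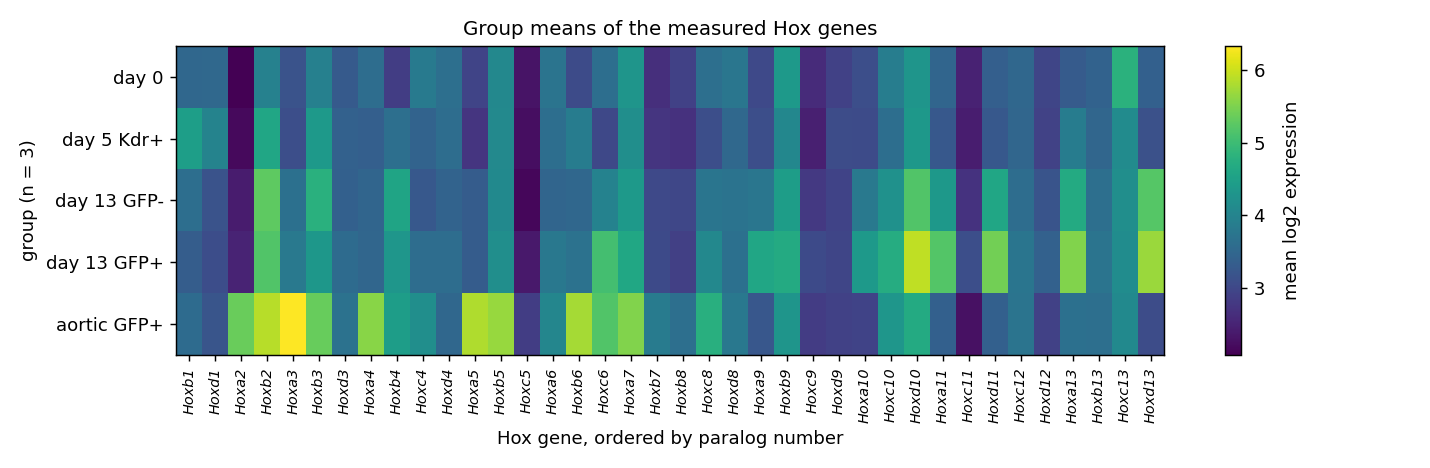
Mean log2 expression of the measured Hox genes in the 5 groups of 3 samples, ordered by paralog number. Hoxa2, Hoxa3 and Hoxa5 are highest in the aortic cells, and Hoxd13, Hoxd11 and Hoxa13 in day 13 GFP+ cells.

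Each day 13 sample was also placed by its distance to the mean aortic profile, the root mean square log2 difference over 23185 named genes. The distance was 0.925 ± 0.013 for GFP+ and 1.00 ± 0.0357 for GFP- samples (SD, n = 3), a difference of -0.0793 (exact two-sided permutation p = 0.1, the smallest that 3 against 3 samples can give). In 3 of 3 pairs of equal number the GFP+ sample lay nearer the aortic mean. The difference between the sorts was compared across the 23185 genes with the difference between aortic and day 0 cells, which gave Pearson r = 0.374 and Spearman rho = 0.346, across genes that are not independent replicates. In the 3 pairs taken singly r was 0.318, 0.312 and 0.32. Of 475 named genes higher in GFP+ than GFP- cells, 385 (81.1%) were higher in aortic than day 0 cells, where 56% of all named genes were, and of 599 lower genes 448 (74.8%) were lower.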

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

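The tests in this part were planned, except the naming of the single genes, which were chosen after their values were seen, and the tally and simulation at the end, which were added after the data were seen. Against day 5, 1 gene rose in day 13 GFP+ cells and fell in GFP- cells, and 11 genes did the opposite, each with a difference between the sorts that passed its own test. Slit3, a guidance ligand gene, changed by 0.475 in GFP+ and -0.427 in GFP- cells, a difference of 0.902 (limma adjusted p = 0.000426). The 11 others were Atp8a1 (-1.34 and 1.02, adjusted p of the difference 8.65e-07), Cd59a (-1.17 and 1.21, 2.48e-06), Plet1 (-0.722 and 1.86, 1.9e-06), Reep6 (-1.51 and 0.82, 1.16e-06), Slc16a1 (-1.21 and 0.869, 2.32e-06), Asb4 (-0.998 and 1.29, 2.28e-05), Fgf5 (-0.857 and 1.22, 0.000213), Grb7, Clcn3, Celf2 and Bcam. None of the 12 is in one of the 27 lists. Single samples were not tested against their groups of 3. Of 5781 probe sets called in both sorts, 5769 moved the same way and 12 in opposite ways, where groups simulated with no change had a mean of 0 called in both. The sorts share the day 5 samples, so a common sign is partly built in: over all probe sets 80.3% had the same sign, against 66.6% in simulated groups with no change, and 76.2% when simulated day 13 samples of equal number were also correlated at 0.466, the mean of the 3 pairs. Independent lists of these sizes would share 433 that rose in both and 594 that fell in both, where 2562 and 3207 did, and would hold 500 and 514 opposite ones in place of 1 and 11. Part of each excess may come from the shared samples, which were not split into separate references, and from any pairing of the sorts, so it is not taken as a shared effect.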

How the results depend on the processing

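The replicate block on the 6 day 13 samples and leaving out both day 13 samples numbered 3 were tests chosen only after the result was seen; the others were planned. Of the values of 429 named gene results under the alternatives, 7213 kept their direction and side of the threshold, 95 passed newly and 243 no longer passed. For 135 list results the counts were 1791, 45 and 67. A further 55 list values turned direction, all for lists that did not pass in the main fit. No result that passed in the main fit turned direction. The fold moved by at least 1.5 times without some single sample in 22 of the 429, in 20 of them without a day 13 sample numbered 3. Of the 429, 114 no longer passed under treat with a log2 change of 1, which tests against a larger change; it gave 518 higher and 682 lower at day 5 against day 0, 558 and 271 for GFP- against day 5, 864 and 725 for GFP+ against day 5, 1 and 30 between the sorts, and 902 and 814 for the aortic cells. With an estimated correlation 9, 8 and 6 lists passed for GFP- and GFP+ against day 5 and for the aortic cells, and with fry 17 passed at day 5 and 20 for the aortic cells; fry asks another question. Array weights gave 4599 and 5503 for GFP- against day 5 and 1383 and 1562 between the sorts. With only the 2 groups, whose spread rests on fewer samples, the sorts gave 193 higher, 74 of them 2-fold, and 266 lower. The block on the 6 day 13 samples gave 1045 higher and 1085 lower between the sorts. The planned block as a fixed effect on 12 samples gave 4085 and 3907 at day 5, 3356 and 3850 for GFP-, 3880 and 4575 for GFP+, and 635 and 827 between the sorts; as a random effect with each aortic sample its own block (consensus correlation 0.0626) it gave 571 and 700 between the sorts and 4451 and 4915 for the aortic cells. A fixed block was not run for the aortic comparison, since nothing ties aortic number 3 to the cultures numbered 3. With genes above the median level, fewer genes were tested, 2545 were higher in the aortic cells, 6 lists passed there, the distance difference was -0.1103 and the correlation with the aortic effect 0.4354; that correlation was 0.3661 after cyclic loess and 0.3461 without both day 13 samples numbered 3. Where no reason is named, the cause was not tested. Leaving out 1 sample gave 3150 to 3504 higher and 2973 to 3293 lower at day 5, 2587 to 3110 and 2936 to 3621 for GFP-, 3132 to 3325 and 3756 to 4009 for GFP+, 307 to 537 and 346 to 584 between the sorts, and 3640 to 4790 and 4257 to 4800 for the aortic cells; the distance difference ran from -0.09435 to -0.05956 and the correlation from 0.3386 to 0.3778. With both samples numbered 3 out, the distance difference was -0.06665 (exact permutation p = 0.333, the smallest that 2 against 2 samples can give). A mean over probe sets of a gene was not run, since each gene has 1 probe set. Genes near the array's background were not separated from unexpressed ones.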

Other observations

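The tests of the leukocyte and endothelial lists in the aortic cells were chosen only after the result was seen, as were the block and the fit without both day 13 samples numbered 3. The tests of the samples numbered 3, the sort effect, the imprinted genes and Xist were chosen after those patterns were seen. Their bounds were set before each test was run. The genes in this part were chosen after their values were seen. Several imprinted genes were high at day 13 and low in the aortic cells, though not all of them. Igf2 stood at 6.03 at day 0, 8.14 at day 5 and 10.96 in GFP+ cells, and was lower at 6.67 in the aortic cells (limma adjusted p = 7.41e-11). Plagl1 (-4.59), Peg3 (-4.06), Dlk1 (-3.92) and Meg3 (-2.93) were lower in the aortic cells by limma, while Grb10 (2.31) and Igf2r (1.75) were higher and Cdkn1c (-0.635, adjusted p = 0.207) and Phlda2 (-0.0199, 0.952) did not pass. Myocd stood at 3.31 at day 0, 4.79 at day 5, 6.97 in GFP-, 5.53 in GFP+ and 9.24 in the aortic cells, so the sort in which the contractile list was higher had the lower level.

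The deviations of the day 13 samples numbered 3 from those numbered 5 and 6 correlated across genes between the sorts at 0.597. The single genes named here were picked for large deviations of the same sign in both sorts, so their agreement follows from that choice. In the GFP+ and the GFP- sample the tendon gene Tnmd deviated by -5.53 and -4.98, Thbs4 by -4.13 and -3.6, Penk by -3.52 and -4.76 and Ogn by -3.3 and -4.66, while Serpina3n (2.71 and 2.45) and the hypoxia-responsive Ndrg1 (1.6 and 1.74) were higher. The glycolysis list had medians of 0.765 and 0.95 and the fibroblast list -0.958 and -0.601. Some other lists went opposite ways in the GFP+ and the GFP- sample, such as proliferation (-0.27 and 0.305) and immediate early genes (-0.242 and 0.0813).

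The 2 deviations of the arrays numbered 3 correlated across genes at 0.597 after cyclic loess, as before it. Cyclic loess moved no sample median by more than 0.151, so this argues only against shifts of that size and leaves other effects of scaling open. A culture less advanced along the course from day 5 stays open: the deviations correlated with that course at -0.0911 and -0.239, 1 of them weaker than the bound set for it. Culture conditions such as oxygen, and a separate experiment for number 3, may also contribute and were not tested.

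Between the sorts, matrix and contractile genes were higher and endoderm and epithelial genes lower in GFP+ cells. If GFP- samples were GFP+ cells diluted by cells without mesenchymal or cardiac transcripts, matrix and cardiac genes would fall alike in GFP- cells. In the 3 pairs the median matrix effect exceeded the median cardiac effect by 1.5, 1.14 and 1.21, taken over the 8 cardiac genes that rose from day 5 to day 13 in GFP+ cells (1.29, 1.17 and 0.978 over the whole cardiac list), which argues against such dilution as the whole cause, though not against added cells that bring cardiac transcripts. With both samples numbered 3 left out, 9 endoderm members were lower, and the mean differences by limma were -1.63 for the endoderm, -1.46 for the epithelial, 0.85 for the matrix and 0.43 for the contractile list (-1.51, -1.41, 0.99 and 0.51 with all samples), so those samples alone do not account for the direction of these 4 lists. A hypothesis from these values is that the GFP- fraction may hold endoderm-like and endothelial cells beside early smooth muscle cells, and single-cell data would be needed to test it. Cardiac-like cells are not set apart in the GFP- fraction, since the cardiac list did not pass between the sorts (camera adjusted p = 0.239). That list passed as lower in GFP+ cells without GFP- sample 3 (0.00116) and under the block (0.035), so this stays open.

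In the aortic GFP+ cells, leukocyte and endothelial lists were higher than in day 13 GFP+ cells. The leukocyte list kept a median shift of 0.918 after cyclic loess. That scaling moved no sample median by more than 0.151, so the test weighs only on shifts of that size and leaves other effects of scaling open. Other aortic cells carried in the samples may contribute and stay open: 33.3% of the leukocyte list (Ptprc, Csf1r, Cd14 and Cd3e) and 29.4% of the endothelial list (Erg, Emcn, Esam, Flt1 and Plvap) were higher than in each of the 4 other groups, against 10.9% of all probe sets. Members already high in iPSC, such as Pecam1 and Laptm5, may fail this test even if such cells are present. The shares do not single out these lists. They were 30% for adipocyte, 31.6% for matrix, 50% for fibroblast and 100% for immediate early and dissociation stress genes, and 0% for epithelial and endoderm genes. The purity of the GFP sort was not measured here, and expression by the aortic muscle cells themselves was not tested.

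For imprinted genes as a wider group, the 18 listed genes other than H19, Mest and Slc38a4, with those named above among them, had a median of -0.845 in the aortic comparison (10 lower, 2 higher, limma camera p = 1.1e-05, and 0.00498 with an estimated correlation), short of the -1 set beforehand, which leaves open whether the whole group moves. Xist rose from 5.49 at day 0 to 7.15 at day 5, 8.27 in GFP- and 8.20 in GFP+ cells, and stood at 9.46 in the aortic cells. At day 5, 942 X-linked genes changed by -0.0923 relative to 22229 autosomal genes (-0.369 for the 384 X-linked genes above the median mean level). Against day 0 the other medians were -0.102 in GFP-, -0.0927 in GFP+ and -0.0884 in aortic cells, and limma camera placed X-linked genes lower in all 4 other groups (adjusted p over the 4 = 0.00388, 0.00436, 0.00667 and 0.0463 from day 5 on). All 4 share the day 0 samples, so they are not separate supports. The aortic cells are primary cells and not a later stage of the culture. The day 5 median fell short of the 0.1 set beforehand, which leaves X inactivation open. For the changed genes of each comparison, 10 splits of 6 samples are too few for a share under 0.05: 1 split, the real one, gave as many, with 7249, 6542, 7867, 1142 and 9372 changed genes in the order of the report against 0 in the highest other split. Every other split mixes both groups on each side, so their difference enters the spread and few calls can arise. The 0 is therefore no evidence of its own.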
